A study of Mus musculus with 6 samples.

How the data were processed

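RNA from full-thickness skin of 6 samples, 3 irradiated with vehicle (UV) and 3 irradiated with BMS-202, was assayed with the nCounter Mouse Inflammation V2 panel, per the labels, after column extraction of total RNA. The values form 1 table of 254 genes, 248 endogenous and 6 housekeeping, with 6 positive and 8 negative spike-in control rows. The deposited gene values are a scaled signal: probe counts multiplied by a factor per sample. The scaling was read from the values, since Gapdh is 6417.31 in all 6 samples and 100% of gene values above the floor are whole multiples of a single step per sample (to within 0.006 plus a millionth of the value). Deposited gene values that would fall below 20 are written as 20, and the spike-in control rows are unscaled counts. The software, the handling of background and the choice of Gapdh as sole reference are not given in the sources used here.

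Groups were taken from the labels' treatment field. The labels state 3 mice per group but do not tie each sample to a mouse. Dividing by the step gave the count behind each gene value, used only for depth, for comparing replicates with counting noise and for checks against the control probes. Steps were 0.839 to 0.927 with UV and 1.09 to 1.21 with BMS-202, so the floor of 20 stood for up to 23.8 counts with UV, and 193 genes per UV sample and 224 per BMS-202 sample on average exceeded the negative control limit (mean + 2 SD). Replicates were compared with a chi-square test over the genes above the floor in all samples of a group. The largest extra coefficient of variation beyond counting noise that remained compatible with the data, in 200 simulations per group, was 1.5% with UV and 3.5% with BMS-202.

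Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(value + 1), over endogenous genes above 20 in at least 3 of the 6 samples (240 genes), with Benjamini-Hochberg adjustment at 0.05 and no fold threshold. Every adjusted p of a gene comes from limma and every adjusted p of a list from limma's fry, or from camera where named. Log2 differences are UV plus BMS-202 minus UV on the log2(value + 1) scale, which understates changes of low genes, while folds are ratios of group means. A fold against a group with all 3 samples at the floor was computed against 20 and is given as a lower bound, as is a fold against a group mean under the highest negative control limit of its samples (26.6 with UV and 45.3 with BMS-202 after scaling), and list medians hold such genes at that bound. The design, gene lists, rule for named genes and most alternatives were fixed before the data were examined. After rescaling to genes, spike-ins or the median, 1 floor was set for all samples at the highest rescaled 20. A scaling that raises the BMS-202 samples therefore leaves the difference of genes at the floor in UV skin almost as it was. Low UV values above 20 can also lie under this raised floor and are set to it, which shrinks or hides their differences.

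The lists were CXC chemokines and neutrophil recruitment, CC chemokines, interferon-induced genes, IL-1 family and inflammasome, acute inflammatory mediators, NF-kB, AP-1 and MAPK, complement, Toll-like receptors, prostaglandin and leukotriene genes, T cell cytokines, tissue repair, NRF2, and markers of macrophages, antigen-presenting cells, neutrophils, T cells, eosinophils and mast cells, muscle and adipocytes. The lists overlap in several genes, and the adipocyte list has 1 gene and was not tested as a list. Lists with at least 3 tested members were tested with fry's directional p, which asks whether the genes of a list move on balance in a single direction and does not compare them with other genes, and adjusted over 19 lists. Named genes were the 12 with the largest log2 difference in each direction among those past the threshold, the 2 members of each list with the smallest p, the housekeeping genes, and Il6, Tnf, Il1b, Ptgs2, Ifng and Il10. Genes named beside these in the report, such as Fos, Oas1a, Mx2, Ifi44, Cxcl10, Nos2, Cd4, Ccl21a, Mafg and Il11, were chosen after their values were seen. Results of some single genes, among them a gene that the naming rule picks, are not reported here, and one gene was left out of the floor gene figure and of the tally of genes of other tissues. Of the gene symbols, 247 were found in the RefSeq mouse table (GRCm38.p6), 6 as synonyms and 1, Mef2c_Mm, not. The sources name no genome build, so no coordinates are given.

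Alternatives, each changed alone, were scaling to 6 housekeeping genes, the panel median or quantiles, no filter, a filter at 50, a pseudocount of 10, values under 20 set to 20, limma without trend, with robust estimation or with array weights, a replicate block, leaving out each sample, camera with preset and estimated correlation, exact permutation of list means, and unadjusted p. After the data were seen, scaling to the positive spike-in controls, scaling to the 5 housekeeping genes without Gapdh, a 2-fold count with each group as 1 sample, and a count without genes at the floor in a whole group were added. The pipeline was tested on data simulated from the UV and BMS-202 comparison (248 genes, 60 of them changed because the panel is small, UV means at each sample's depth with counting noise alone, 20 simulations): it called 54.3% of genes changed 1.25-fold, 80.0% of those changed 1.5-fold, 94.9% of those changed 2-fold and 1.13% of unchanged genes. In these simulations Gapdh was unchanged and a single depth factor per sample applied to every gene. The rates therefore hold only where Gapdh is a sound reference, and they say nothing about calls that follow from the scaling. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.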

Results

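Expression of 254 transcripts was measured in full-thickness back skin of SKH-1 mice, an immunocompetent hairless strain, with the nCounter Mouse Inflammation V2 panel, an assay that counts RNA molecules bound by barcoded probes without amplifying them. Both groups received a single acute exposure to solar simulated ultraviolet light, at 90 kJ/m2 UVA and 6 kJ/m2 UVB, and skin was taken 24 h later. The UV group (n = 3) was given the acetone vehicle on the skin, and the UV plus BMS-202 group (n = 3) was given 200 µl of 8 mM BMS-202, a small molecule that binds and blocks PD-L1, an immune checkpoint ligand. Each was applied 3 times: 24 h before, 1 h before and directly after irradiation. The comparison asks how topical PD-L1 blockade alters stress and inflammatory gene expression in UV-exposed skin. Unirradiated skin was not analysed here, so a difference does not say whether a gene moved toward or away from its level before exposure. Cd274, which encodes PD-L1, and Pdcd1, which encodes its receptor PD-1, are not on the panel.

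The depth of the samples differed between the groups. Total gene counts recovered from the scaled values were 142900 to 160891 in the UV samples and 41537 to 45040 in the UV plus BMS-202 samples, whereas the positive spike-in control probes totalled 78281 to 90723 and 67957 to 73592 counts. The glycolytic gene Gapdh, set to the same value of 6417 in every sample, made up 4.75 to 4.85% of gene counts with UV and 12.6 to 13.0% with BMS-202. Between 49 and 51 genes of each UV sample and 18 to 19 genes of each UV plus BMS-202 sample were listed at the floor value of 20. Over all detected genes the 3 samples of a group differ by little more than sampling noise: the chi-square statistic per degree of freedom was 1.11 with UV (p = 0.0636, 200 genes) and 1.10 with BMS-202 (p = 0.0672, 232 genes). In genes with over 100 counts the BMS-202 samples differed beyond sampling noise, with a chi-square statistic per degree of freedom of 1.33 (p = 0.000378, 124 genes), against 1.13 with UV (p = 0.0556, 149 genes). The labels give 3 mice per group and the samples were kept as 3 per group, but all SDs, standard errors and p-values below measure a spread close to counting noise, which may be technical.

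With Gapdh fixed by the scaling, the other 5 housekeeping genes read lower in every sample given BMS-202. Cltc, the clathrin heavy chain gene, read 5727 ± 92.8 with UV and 586 ± 13.4 with BMS-202 (mean ± SD, n = 3), 9.77-fold lower. Gusb was 10.6-fold lower, Hprt 6.32-fold and Pgk1 7.74-fold, while the tubulin gene Tubb5 was 2.33-fold lower. These directions hold relative to Gapdh, and on the log2 scale Tubb5 turned to 1.04 with values rescaled to all 6 housekeeping genes, 1.49 with the 5 other than Gapdh and 0.85 with quantile normalization, and Hprt to 0.051 with those 5. Per positive spike-in count, Gapdh with BMS-202 was 0.767 of its level with UV. The other 5 genes were 0.0723 (Gusb), 0.0785 (Cltc), 0.0998 (Pgk1), 0.121 (Hprt) and 0.328 (Tubb5) of theirs. The spike-in count here and in spike-in scaling is the geometric mean of the 6 positive controls, 2228 with UV and 2186 with BMS-202. These means lie closer together than the totals, because the low controls POS_F and POS_E read 1.56 and 1.06 times their UV counts. The other positive controls read lower with BMS-202.

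**Figure D1:**
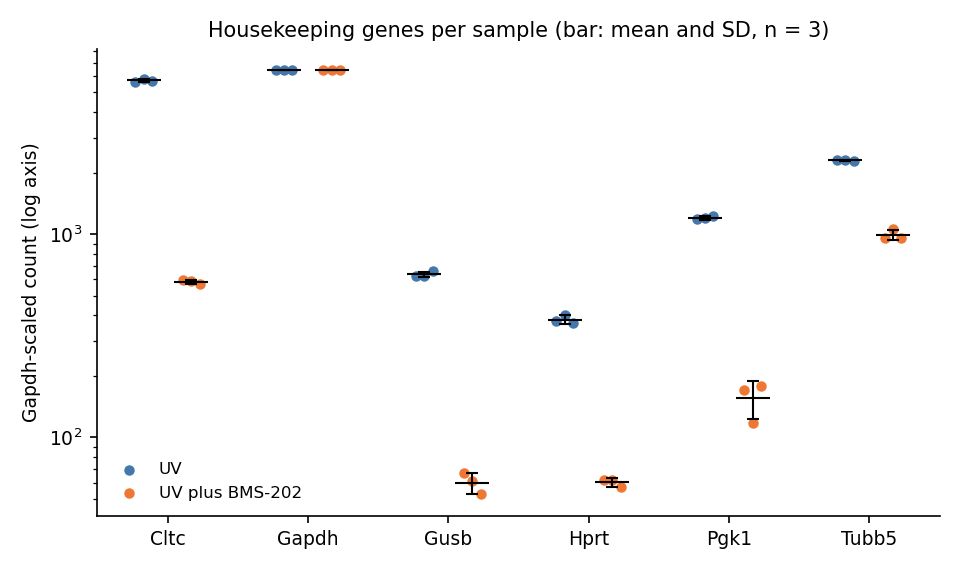
Gapdh-scaled counts (log axis) of the 6 housekeeping genes in each of the 3 UV samples and 3 UV plus BMS-202 samples, with mean and SD as bars. Gapdh is fixed at 6417 by the scaling, and Cltc lies at a mean of 5727 with UV and 586 with BMS-202; relative to all 6 genes, to the 5 without Gapdh or after quantile normalization Tubb5 lies higher with BMS-202, and Hprt does so relative to the 5.

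Skin treated with BMS-202 differed from vehicle-treated UV skin in most of the inflammatory panel. The largest measured difference was that of Mx1, an interferon-induced antiviral GTPase gene, which rose 36.2-fold, from 76.3 ± 6.22 to 2765 ± 128 (mean ± SD, n = 3). The rise of Ifna1, at least 32.4-fold from the floor, may be larger. Il18, which encodes a cytokine matured by the inflammasome, fell at least 20-fold, from 679 ± 36.2 to 33.9 ± 5.00, and Mef2c at least 17.7-fold to the floor. Both values with BMS-202 lie under the negative control limit, so the order of the largest falls is not known. Transcripts of stress signalling, NF-kB and tissue repair genes were lower relative to Gapdh, with the transcription factor gene Hif1a 9.59-fold lower. Most panel genes at these lists' levels in UV skin were lower too, and the list means turned positive with housekeeping scaling. None of these 3 lists passed with camera and an estimated correlation (adjusted p = 0.201 each), and 3 AP-1 and MAPK genes and Il11 rose. Of 45 genes at the floor in all UV samples, 38 were above it in all BMS-202 samples, T cell cytokine genes such as Ifng and Il21 among them. Mx1 was higher, and Il18 and Hif1a lower, under all 6 ways of scaling that were tried. The housekeeping gene Cltc read lower under all 6 too, and relative to Gapdh it fell about as far as Hif1a (log2 -3.29 and -3.26).

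Relative to Gapdh, as the values were deposited, 92 of 240 tested genes were higher with BMS-202, 132 were lower and 16 did not pass (limma, adjusted p under 0.05), with a median log2 difference of -0.56. Scaling to the 6 housekeeping genes moved that median by 1.91 and turned the split to 184 higher and 34 lower. The 5 housekeeping genes without Gapdh moved it by 2.10 (202 higher, 15 lower), the panel median by 0.48 (108 and 116), quantile normalization by 0.66 (99 and 96) and the positive spike-in controls by -0.37 (81 and 142). Across these 6 scalings 66 genes were called higher in every one, 37 of them at the floor in all 3 UV samples, 15 genes were called lower in every one, and 109 had calls in both directions. Housekeeping and panel-median scaling leave the difference of genes at the floor in UV skin almost unmoved, because the floor is rescaled too. Directions below are relative to Gapdh unless a scaling is named.

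**Figure D2:**
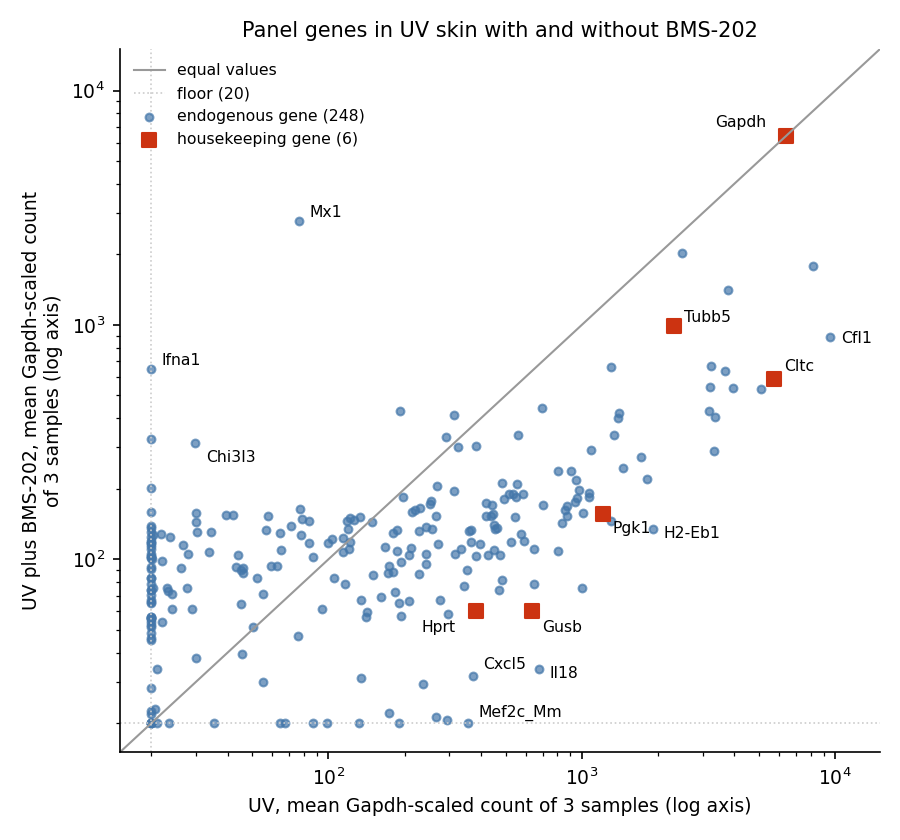
Mean Gapdh-scaled count of 3 UV plus BMS-202 samples against that of 3 UV samples (both log axes) for the endogenous genes (circles) and 6 housekeeping genes (squares), with the line of equal values and the floor of 20 dotted. Mx1 lies farthest above the line, at 76.3 and 2765, and Il18 at 679 and 33.9. Under the other scalings the line of equal values shifts, by 2.26 log2 units for the 6 housekeeping genes in genes well above the floor.

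Of the 12 genes that rose most, 9 were listed at 20 in all 3 UV samples, so that their fold is a lower bound. Ifna1, an interferon alpha gene of a large near-identical family, was at least 32.4-fold higher (649 ± 44.8, n = 3). C9, Crp, Kng1 and Mbl2, whose products are plasma proteins made mainly in liver, were at least 10.1, 6.95, 6.55 and 6.20-fold higher. The leukotriene receptor gene Cysltr2 was at least 6.81-fold and Il21 at least 7.93-fold higher. Chi3l3, a gene of the macrophage marker list, rose 10.5-fold from 29.8 ± 3.98 to 314 ± 7.29. Il23a, which encodes a subunit of IL-23, rose at least 6.27-fold to 127, with 2 of 3 UV samples at the floor. All of these genes were higher under all 6 scalings, although 3 of these cannot move a gene from the floor in UV skin. The values of 38 genes at the floor in UV skin and above it in all BMS-202 samples lay between 45.3 and 648.6, with a median of 83.5, and their lowest mean unscaled count was 39.0, against a highest negative control limit (mean + 2 SD) of 37.9 counts.

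The genes that fell most were spread over several functions. H2-Eb1, a class II antigen presentation gene, fell 14.2-fold (1904 ± 5.48 to 134 ± 29.4, n = 3), Tgfb1 13.3-fold, the neutrophil chemokine gene Cxcl5 at least 11.6-fold (to 31.9, under the negative control limit), the G protein gene Gnas 11.5-fold and the actin-severing factor gene Cfl1 10.8-fold (9585 ± 47.7 to 891 ± 53.2). The complement gene C3 fell 8.95-fold. Mef2c, listed as Mef2c_Mm, and Ly96, the TLR4 co-receptor gene, were at the floor in all 3 BMS-202 samples and at least 17.7-fold and 9.49-fold lower. Fxyd2 was at least 14.3-fold and the repressor gene Bcl6 at least 12.5-fold lower, each with 2 of 3 BMS-202 samples at the floor. These 10 genes were lower under all 6 scalings. The housekeeping genes Cltc, Gusb and Pgk1 also read lower under all 6, so this alone does not set a gene apart from them. Relative to Gapdh, C3 (log2 -3.16) fell less than Cltc (-3.29).

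**Figure D3:**
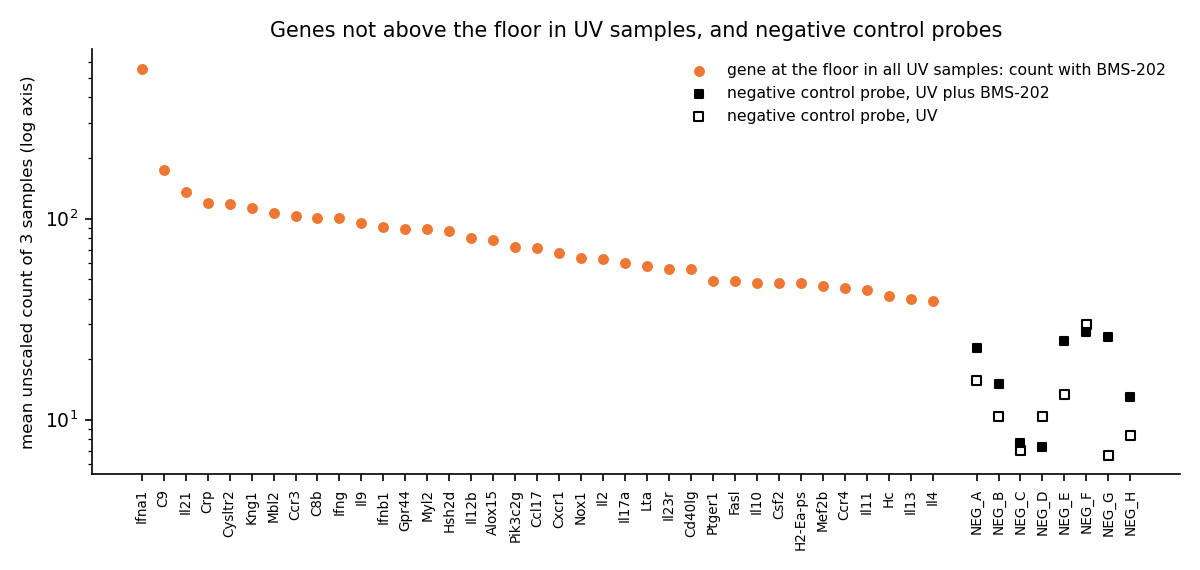
Mean unscaled count (log axis) in 3 UV plus BMS-202 samples of 37 of the 38 genes listed at the floor in all 3 UV samples and above it with BMS-202, beside the 8 negative control probes in both groups (n = 3 each). Ifna1 lies highest, and the lowest gene has 39.0 counts.

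Interferon-induced genes rose on balance, with 12 of 17 higher and 5 lower (median log2 0.91, limma fry adjusted p = 7.20e-05), and the mean kept its sign under all 6 scalings. The list did not pass with camera and an estimated correlation (adjusted p = 0.332). Besides Mx1, Mx2 rose 5.28-fold, Ifi44 at least 5.25-fold and the chemokine gene Cxcl10 4.33-fold, each higher under all scalings. Irf1, an interferon-responsive transcription factor gene, fell 4.09-fold (426 ± 10.8 to 104 ± 6.09, n = 3) and Oas1a fell at least 4.31-fold, to values under the negative control limit, but both turned to higher values under both housekeeping scalings.

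Stress kinase and NF-kB genes fell relative to Gapdh, as did most panel genes at their levels in UV skin. The lists' median UV levels were 484 (AP-1 and MAPK) and 271 (NF-kB). Of panel genes with UV levels of 300 to 1000, 55 of 56 read lower (median log2 -1.81). From 100 to 300, 49 of 58 read lower (-0.81). Of 23 tested AP-1 and MAPK genes 20 were lower and 3 higher (median log2 -1.89, fry adjusted p = 9.52e-07, and adjusted p = 0.201 with an estimated correlation), but the list mean turned to 0.41 with the 6 housekeeping genes. The kinase genes Map2k1 and Mapk3 fell 5.82-fold (1070 ± 14.7 to 184 ± 3.13, n = 3) and 6.27-fold, and both turned to small positive values (0.17 and 0.06 on the log2 scale) with the 5 housekeeping genes, Mapk3 without passing (adjusted p = 0.287). Fos was 4.15-fold lower, turning to 0.19 with the 6 housekeeping genes without passing (adjusted p = 0.178) and to 0.64 with the 5, and it had no call with quantile normalization (adjusted p = 0.0752). All 13 NF-kB pathway genes were lower (median log2 -1.20, fry adjusted p = 1.10e-06, and adjusted p = 0.201 with an estimated correlation), but the list mean turned to 1.02 with the 6 housekeeping genes. Tollip, an adaptor of interleukin 1 receptor and TLR signalling, and the kinase gene Map3k7 fell 3.95-fold and 3.71-fold, and both turned to higher under both housekeeping scalings. NRF2 pathway genes had 4 of 5 lower and Mafg higher (median log2 -0.83, fry adjusted p = 5.74e-05), turning to a mean of 1.55 with the 6 housekeeping genes and 0.36 with quantile normalization. With camera and an estimated correlation the adjusted p was 0.863. Nfe2l2, which encodes NRF2, fell 3.48-fold and Mafk 1.84-fold, and both turned to higher under both housekeeping scalings. Nfe2l2 had no call with quantile normalization (adjusted p = 0.900). Mafg rose 1.32-fold, without passing with spike-in scaling (adjusted p = 0.735).

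Among cytokines and acute mediators, Il1b fell 2.86-fold (436 ± 24.3 to 152 ± 4.50, n = 3), Il6 1.73-fold (187 ± 3.24 to 108 ± 8.68) and the inducible cyclooxygenase gene Ptgs2 1.72-fold (227 ± 10.5 to 132 ± 24.4), and all 3 turned to higher under both housekeeping scalings. With quantile normalization none of the 3 had a call (Il1b -0.13 on the log2 scale, adjusted p = 0.102, Il6 -0.37, adjusted p = 0.130, and Ptgs2 0.063, adjusted p = 0.805). Tnf rose 1.68-fold, from 64.9 ± 8.13 to 109 ± 5.21, and was higher under all 6 scalings. Of panel genes with UV levels of 20 to 100, 52 of 63 read higher (median ratio 2.01), so this rise does not set Tnf apart from them. The acute mediator list had 5 genes higher, 8 lower and 1 not past (median log2 -0.70, fry adjusted p = 4.32e-04, direction down), and its mean of -0.33 turned to 1.22 with the 6 housekeeping genes and 0.0547 with the panel median. Camera with an estimated correlation gave this list an adjusted p of 0.986. In this list the nitric oxide synthase gene Nos2 rose at least 5.88-fold and was higher under all scalings, whereas the protease gene Mmp9 fell 8.24-fold and was lower under all scalings, without passing with the 5 housekeeping genes (adjusted p = 0.0731). IL-1 family and inflammasome genes had 9 of 11 lower, 1 higher and 1 not past (median log2 -1.45, fry adjusted p = 1.59e-05), but the list mean turned to 0.72 with the 6 housekeeping genes. This call ended with camera and an estimated correlation (adjusted p = 0.662). In this list the receptor gene Il1r1 fell 5.53-fold, turning to 0.24 with the 5 housekeeping genes. It passed with neither the 5 (adjusted p = 0.0688) nor the 6 (adjusted p = 0.0829).

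Chemokine lists were split. CC chemokine genes had 5 higher, 6 lower and 2 not past; their median was 0.11 but the mean, -0.35, and the test (fry adjusted p = 2.24e-04) pointed down, and the mean turned to 1.33 with the 6 housekeeping genes and 0.0494 with the panel median. An estimated correlation in camera raised the adjusted p to 0.986, and quantile normalization to 0.918 with fry. The monocyte chemokine genes Ccl2 and Ccl8 fell 5.32-fold (860 ± 7.53 to 162 ± 12.3, n = 3) and 4.95-fold, turning to 0.30 and 0.40 on the log2 scale with the 5 housekeeping genes. With the 6, neither had a call (adjusted p = 0.0803 and 0.487). Ccl21a, a lymphatic chemokine gene, rose 2.24-fold under the deposited scaling and was higher under all others. CXC and neutrophil recruitment genes had 4 higher, 4 lower and 1 not past and no call as a list (median log2 0.11, mean -0.30, fry adjusted p = 0.115, direction down). This list passed fry downward with quantile normalization (mean -0.65, adjusted p = 2.66e-05) and spike-in scaling (-0.65, adjusted p = 1.99e-04), and upward with the 6 housekeeping genes (0.88, adjusted p = 1.79e-05) and the 5 (1.05, adjusted p = 1.07e-05). Cxcl5 was lower, as given above, and the receptor gene Cxcr1 was at least 3.92-fold higher from the floor.

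Of 15 T cell cytokine genes on the panel, 12 were tested and were higher (median log2 1.66). Of these, 11 were at the floor in all 3 UV samples and could pass the filter only by reading above it with BMS-202, so the test of the filtered list is not given. Of the other 3, Il5 and Il22 were at the floor in both groups and Il3 read 22.4 with BMS-202. Without the filter the mean of all 15 was 1.44, and no test is given for it either, since 14 of them were at the floor in UV skin and cannot read lower. Ifng read 117 ± 9.97 with BMS-202 (n = 3), at least 5.85-fold higher, and Il10 read 55.9 ± 3.06, at least 2.80-fold higher. The 6 T cell markers were all higher (median log2 1.53, fry adjusted p = 1.59e-05, and camera adjusted p = 0.201 with an estimated correlation). Of these, Cd40lg, Fasl and Ltb are also T cell cytokine genes, so the lists are not separate evidence. Cd40lg, Fasl and Ccr4 were at the floor in UV skin, where no lower value is possible. The filter admitted these 3 only if higher, so the fry test was partly fixed in advance. Of the 6 markers, Fasl, which encodes a death ligand, was at least 2.83-fold higher. The lymphotoxin gene Ltb was at least 3.13-fold higher, without passing under quantile normalization (adjusted p = 0.0856). Cd4 rose from 64.3 ± 10.5 to 129 ± 6.91 (n = 3) and was higher under all scalings.

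Markers of other cell types moved in both directions. Macrophage and monocyte markers had 8 of 12 lower, 1 higher (Chi3l3) and 3 not past (median log2 -1.67, fry adjusted p = 1.30e-05), turning to a mean of 0.91 with the 6 housekeeping genes. The list did not pass with camera and an estimated correlation (adjusted p = 0.659). In this list the integrin gene Itgb2 fell 8.18-fold (1804 ± 60.6 to 221 ± 10.8, n = 3) and was lower under all scalings. The housekeeping gene Cltc, 9.77-fold lower, was so too. The signalling adaptor gene Tyrobp fell 4.85-fold but turned to 0.43 with the 5 housekeeping genes and 0.13 with quantile normalization. Tyrobp had no call with the 6 housekeeping genes (adjusted p = 0.776). Neutrophil markers, which share Itgb2, had 2 higher, 3 lower and 1 not past (median log2 -0.73, fry adjusted p = 1.59e-05, direction down, turning to a mean of 0.92 with the 6 housekeeping genes). With camera and an estimated correlation the adjusted p was 0.986. Antigen-presenting cell markers had 5 higher and 2 lower (median log2 0.99, fry adjusted p = 4.81e-04), but the mean turned to -0.09 with spike-in scaling. Of the 7, 2 (Ccl17 and H2-Ea-ps) were at the floor in UV skin and so admitted by the filter only if higher. Camera with an estimated correlation gave this list an adjusted p of 0.475, and fry after quantile normalization 0.0677. H2-Eb1 fell, and H2-Ea-ps was at least 2.77-fold higher from the floor. Eosinophil and mast cell markers had 4 higher and 1 lower (median log2 1.14, fry adjusted p = 1.59e-05), 3 of the 5 at the floor in UV skin and so admitted by the filter only if higher. This call ended with camera and an estimated correlation (adjusted p = 0.422). Ccr3 was at least 5.99-fold and Il4 at least 2.27-fold higher. Muscle markers had 2 higher and 2 lower (median log2 -1.23, fry adjusted p = 1.30e-05, direction down), turning to a mean of 0.62 with the 6 housekeeping genes. An estimated correlation in camera raised the adjusted p to 0.986. Among them Ppp1r12b was at least 6.58-fold lower, at the floor in all BMS-202 samples, without passing with the 5 housekeeping genes (adjusted p = 0.260). With these 5 its values in both groups lay at or near the raised floor (-0.014 on the log2 scale), so little difference could show. The adipocyte marker Cfd, a single gene, fell 2.72-fold (492 ± 34.3 to 181 ± 22.5) and turned to higher under both housekeeping scalings. It had no call with quantile normalization (0.13 on the log2 scale, adjusted p = 0.382).

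Tissue repair and growth factor genes had 12 of 13 lower and 1 higher (median log2 -1.53, fry adjusted p = 9.52e-07, and adjusted p = 0.201 with an estimated correlation), but the mean turned to 0.33 with the 6 housekeeping genes. Besides Hif1a and Tgfb1, the growth factor gene Pdgfa fell 5.18-fold, turning to 0.34 with the 5 housekeeping genes, and Il11 was at least 2.56-fold higher from the floor. Complement genes had 7 higher, 10 lower and 2 not past (median log2 -0.67, fry adjusted p = 8.75e-05, direction down), and the mean of -0.21 turned positive under both housekeeping scalings, the panel median and quantile normalization. The list did not pass with camera and an estimated correlation (adjusted p = 0.986). C4a fell 5.94-fold (1456 ± 33.1 to 245 ± 9.93, n = 3), turning to 0.14 with the 5 housekeeping genes. Toll-like receptor genes had 5 higher, 3 lower and 2 not past (median log2 0.12, mean 0.0094, fry adjusted p = 0.132, direction down). They passed fry downward with quantile normalization (mean -0.29, adjusted p = 2.09e-04) and spike-in scaling (-0.33, adjusted p = 0.00272), and upward with the panel median (0.40, adjusted p = 0.00209), the 6 housekeeping genes (1.46, adjusted p = 5.37e-06) and the 5 (1.62, adjusted p = 2.90e-06). Tlr9 was at least 5.70-fold higher and Ly96 lower, both under all scalings. Prostaglandin and leukotriene genes had 7 higher, 7 lower and 3 not past (median log2 -0.09, mean 0.14, fry adjusted p = 0.115, direction up). They passed fry downward with spike-in scaling (mean -0.20, adjusted p = 0.0218), and upward with quantile normalization (0.33, adjusted p = 0.0356), the panel median (0.49, adjusted p = 6.17e-04), the 6 housekeeping genes (1.61, adjusted p = 1.04e-05) and the 5 (1.82, adjusted p = 4.13e-06). The thromboxane receptor gene Tbxa2r was at least 4.98-fold higher, and higher under all scalings.

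**Figure D4:**
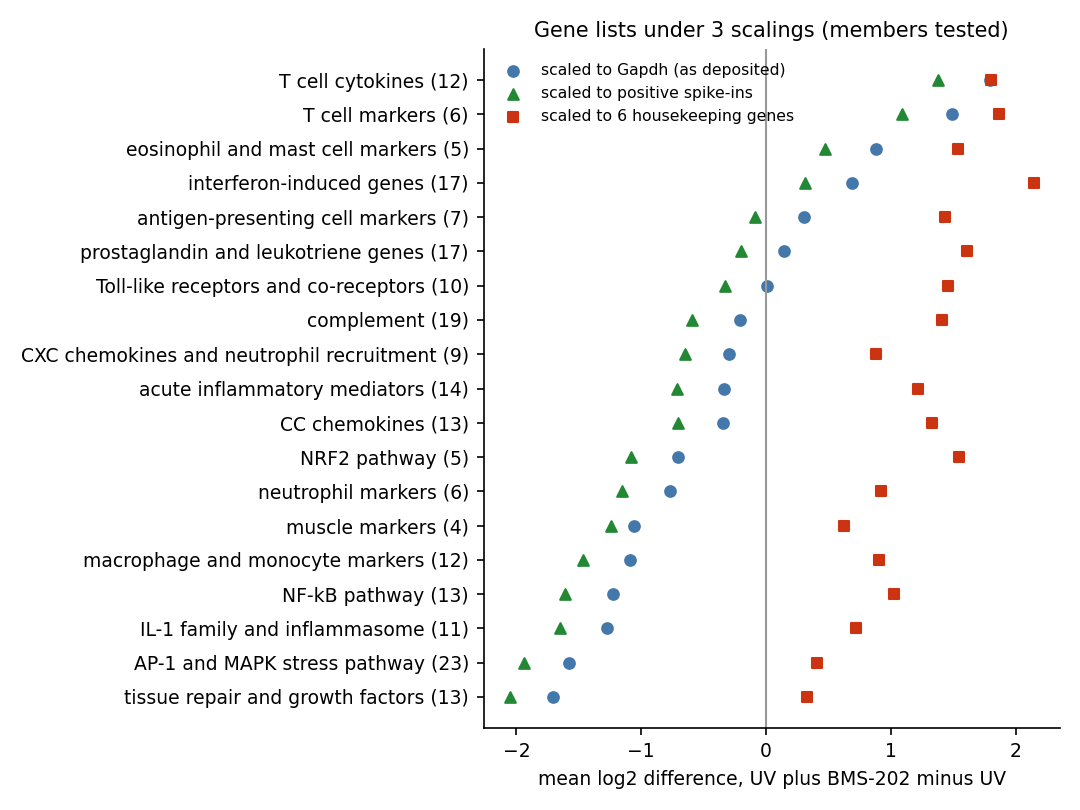
Mean log2 difference (UV plus BMS-202 minus UV, 3 samples each) of the tested members of 19 gene lists under 3 scalings, with the number of tested members in brackets. With the 6 housekeeping genes all 19 means are positive, 11 of them reversed from a called fall relative to Gapdh, and T cell cytokines are positive under each of the 3, with 11 of 12 members at the floor in UV skin.

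In all, 16 of 19 lists passed fry, T cell cytokines by members that the filter admits only if higher, and counts of members adjusted over the list alone were the same as those over all tested genes for all 19 lists. Set against the other panel genes with camera, 5 lists passed with the preset correlation (AP-1 and MAPK, NF-kB, tissue repair, T cell cytokines and T cell markers). With an estimated correlation 0 passed (4 at an unadjusted p under 0.05). T cell cytokines, and T cell markers in 3 of 6 members, again hold genes that the filter admits only if higher. Neither fry nor camera sets a list against genes of like UV level. The exact two-sided permutation test of list means called 0 lists, since 3 samples against 3 cannot give a p under 0.1.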

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

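The tests in this part were chosen after the values were seen. Groups of 3 are too small for a test of single outlying samples, so none was made.

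The spike-in control probes, used in the report only for scaling and as a limit of detection, carried signals that differed between the groups. The mean count of the 8 negative control probes was 12.7 ± 1.49 with UV and 17.9 ± 0.564 with BMS-202 (n = 3), a ratio of 1.41, with all 3 BMS-202 samples above all 3 UV samples (exact permutation p = 0.1, the smallest that 3 against 3 can give). The lowest positive control, POS_F, read 85.3 ± 14.5 and 133 ± 20.6 counts, a ratio of 1.56 in the same direction, while POS_A, the most abundant, had a ratio of 0.823. Of the negative controls 6 read higher and 2 lower (NEG_D 0.710 and NEG_F 0.921 of the UV mean). NEG_G rose most, 3.85-fold, and without it the ratio of the means was 1.24, with all 3 BMS-202 samples still above all 3 UV samples.

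The first pattern weighed is that 38 genes at the floor in all UV samples were above it in all BMS-202 samples. Higher assay background in the BMS-202 lanes is argued against for most of them. Their median unscaled count was 4 times the mean negative control count in the BMS-202 samples, although they were picked for reading above the floor. The median of all 45 genes at the floor in UV skin was 73.7 with BMS-202, above the highest scaled control limit of 45.3. The lowest of the 38, at a mean of 39.0 counts, lay just above the highest unscaled limit of 37.9. Background is therefore not excluded for single low genes. Induction by BMS-202 limited to genes that skin or its immune cells use is argued against as the whole cause, since 5 of 7 genes made mainly in liver or retina rose from the floor too (C8a and Gngt1 did not), but induction of single cytokine genes stays open as a biological explanation. A template that holds every gene in similar amounts, such as genomic DNA, is neither supported nor excluded. Of all 45 genes at the floor in UV skin 75.6% lay within 2-fold of their median with BMS-202. This share lies between the bounds of 80% and 50% set for and against it. Of the 38 genes alone 92.1% did, but these were picked for reading above the floor. Of 194 genes above the floor in all UV samples, 40.2% lay within 2-fold of their median with UV. Ifna1, whose family has 14 names in the gene table, was highest, while 14 genes were at the floor in all BMS-202 samples, and probe positions relative to exons, which could settle this, were not used here.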

How the results depend on the processing

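Scaling to the spike-in controls, scaling to 5 housekeeping genes, the count with each group as 1 sample and the count without floor genes were chosen after seeing the data. Counts of genes and lists stayed within 1.5 times of 92 higher, 132 lower and 16 lists under no filter, a filter at 50, a pseudocount of 10, no trend, robust estimation, array weights, panel-median, quantile and spike-in scaling, unadjusted p and each left-out sample (81 to 108 higher, 96 to 142 lower and 16 to 19 lists over all of these, and 87 to 94, 132 to 134 and 16 to 19 with a sample left out). Setting values under 20 to 20 moved nothing and so tests nothing. The replicate block gave 90 higher, 132 lower and 16 lists and changed no other call; the numbers do not pair the samples, as deviations of same-numbered samples correlated at 0.018, -0.039 and 0.013. With each group as 1 sample, 72 genes were over 2-fold higher and 100 over 2-fold lower, with no test. Without genes at the floor in a whole group, 54 were higher, since fewer genes were counted. The count model was planned only for raw counts and was not run. The floor of 20 limits every fold from or to it, and the lower depth with BMS-202 widens counting noise there.

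With the 6 housekeeping genes, 184 genes were higher and 34 lower, and with the 5 without Gapdh 202 and 15; by construction these scalings raise BMS-202 values well above the floor, by 2.26 and 2.71 on the log2 scale in the median of such genes, and hardly move genes at the floor in UV skin. With camera 5 lists passed with the preset and 0 with the estimated correlation, and exact permutation gave 0 (limma fry 16), where no p under 0.1 is possible. At an unadjusted p under 0.05, camera with the estimated correlation called 4 lists.

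List means that reversed with the 6 and the 5 housekeeping genes were, on the log2 scale, CC chemokines 1.33 and 1.61, IL-1 family 0.72 and 1.03, acute mediators 1.22 and 1.43, NF-kB 1.02 and 1.47, AP-1 and MAPK 0.41 and 0.78, complement 1.41 and 1.65, tissue repair 0.33 and 0.71, NRF2 1.55 and 1.995, macrophage markers 0.91 and 1.246, neutrophil markers 0.92 and 1.18, and muscle markers 0.62 and 0.94. Of the genes named by the rule fixed beforehand, the only ones followed here, those that reversed with both were Cfd 0.81 and 1.26, Il1b 0.74 and 1.19, Il6 1.46 and 1.90, Irf1 0.23 and 0.68, Mafk 1.37 and 1.82, Map3k7 0.37 and 0.82, Nfe2l2 0.46 and 0.91, Ptgs2 1.45 and 1.90, Tollip 0.28 and 0.73, and Tubb5 1.04 and 1.49. With the 5 alone, of these genes C4a reversed to 0.14, Ccl2 to 0.30, Ccl8 to 0.40, Il1r1 to 0.24, Map2k1 to 0.17, Mapk3 to 0.063, Pdgfa to 0.34, Tyrobp to 0.43 and Hprt to 0.051. Of these lists and genes, quantile normalization reversed complement (0.27), NRF2 (0.36), Cfd (0.13), Ptgs2 (0.063), Tyrobp (0.13) and Tubb5 (0.85), where the cause was not tested. Over all tested genes 109 had calls in both directions among the scalings. The panel median reversed complement (0.17), CC chemokines (0.049) and acute mediators (0.055), and spike-in scaling reversed antigen-presenting cell markers (-0.089), by shifts of 0.48 and -0.37 in the median gene.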

Other observations

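The gene groups and tests in this part were chosen after the values were seen.

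Single genes of the actin cytoskeleton and its small GTPases, on none of the lists and not tested as a group, read lower with BMS-202 relative to Gapdh, as did 132 of the 240 tested genes. Cfl1 fell 10.8-fold and passed under all 6 scalings, and Rac1 fell 7.35-fold (3964 ± 30.4 to 540 ± 32.6, n = 3) and was lower under all 6, without passing with the 5 housekeeping genes (limma adjusted p = 0.0746). Rhoa fell 5.89-fold, turning to 0.15 on the log2 scale with the 5 housekeeping genes without passing (adjusted p = 0.137), and had no call with quantile normalization (adjusted p = 0.146). Cdc42 fell 4.57-fold, Ptk2 3.91-fold and Limk1 1.98-fold, and all 3 turned to positive values under both housekeeping scalings, Cdc42 without passing with the 6 (0.068, adjusted p = 0.224).

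Single genes of epithelial and innate cytokine signalling outside the lists, also not tested as a group, went both ways. Tslp, which encodes an epithelial cytokine, rose 4.32-fold (30.1 ± 3.41 to 130 ± 2.53, n = 3), Tnfsf14 4.78-fold, Irf3 3.81-fold, Il7 at least 3.51-fold and Ager 3.19-fold, each under all 6 scalings. Il12b and Ifnb1 were at least 4.62-fold and 5.29-fold higher from the floor. Irf5 fell 3.12-fold and Il6ra 3.39-fold, and both turned to higher under both housekeeping scalings. Il15 fell from 35.5 to the floor. Under the housekeeping scalings the raised common floor lies above its values in both groups, so no difference can show there. Across genes, the difference followed the level in UV skin. Of 63 genes between 20 and 100 with UV, 52 read higher with BMS-202 (median ratio 2.01). Of 26 genes over 1000, 0 did (median ratio 0.169). Several lists lay along this trend. AP-1 and MAPK, tissue repair and IL-1 family genes, which fell, had median UV levels of 484, 448 and 436. T cell cytokines, eosinophil and mast cell markers and T cell markers, which rose, had 20, 20 and 21.7. No list was tested against genes of like UV level.

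The second pattern weighed is that 5 of 6 housekeeping genes fell against Gapdh. A rise of Gapdh alone is argued against, since per positive spike-in count the median of the other 5 genes was 0.0998 of its UV level. Less RNA in the reaction for all genes alike is argued against as the whole cause, since Gapdh kept 7.69 times the ratio of the others. Less RNA together with a template that holds every gene is neither supported nor excluded. The log2 level with BMS-202 rose by 0.306 per unit of the UV level across 181 genes above the floor in all 6 samples. These genes are not independent replicates, and any narrowing of levels would give such a slope, so it cannot point to a cause. The slope leaves out 9 genes above the floor in all UV samples and at it in all BMS-202 samples. Of these, Mef2c (355 with UV), Ly96 (190) and Ppp1r12b (132) had the highest UV levels. Genes like these would go against a template that every probe reads in similar amounts. Probe positions relative to exons were not used here, so these genes do not exclude a template such as genomic DNA. An effect of BMS-202 on the housekeeping transcripts stays open. It is untested why Gapdh would differ, although 3 Gapdh pseudogene names are in the gene table.

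The third pattern weighed is that the 3 samples of a group differ by about counting noise. Repeat assays of a single RNA per group may account for this, since the larger of the chi-square statistics per degree of freedom was 1.11, where an added variation of 20% would give 29.9 with UV and 7.92 with BMS-202. Against counting noise as the only spread stands the statistic of 1.33 in BMS-202 genes with over 100 counts (chi-square p = 0.000378). A single hybridisation deposited 3 times is argued against, since spike-in and gene totals differ among samples (chi-square p = 1.84e-14 with UV and 0.000889 with BMS-202). Separately processed mice stay open, with an extra coefficient of variation of at most 1.5% with UV, as the variation between such mice is not known here.

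Of the 10 splits of the 6 samples into 3 and 3, 1, the real split, called 224 genes and 16 lists, and the highest of the others called 0 genes and 0 lists (limma, also 0 genes at an unadjusted p under 0.05). The splits are too few for a share under 0.05.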
